A study of Mus musculus with 7 samples.

How the data were processed

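The 7 samples are mouse mPFC RNA libraries, 4 from mice labelled as treated with rhTSP1 and 3 from mice labelled PBS. Per the labels' protocols, RNA was extracted with a column kit and 1.3 µg of total RNA per sample entered a SMARTer mRNA library preparation. The deposited table gives raw read counts per gene, as judged from its values, which are whole numbers with different totals per library. The submitters' processing notes name the genome builds GRCm38 and mm10. The aligner, the counting tool, its annotation and whether counting used strand are not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart. Every gene in the table has at least 5 counts over the 7 libraries. Columns were matched to samples by the leading number of each sample's description, and 0 columns belonged to other samples. The 7 libraries were numbered 1 to 4 (TSP1) and 8, 11 and 12 (PBS) in those descriptions. No batch is labelled, and these numbers do not interleave between the groups, so an order effect and the treatment share the same split.

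Gene identifiers were matched to GENCODE M21 (GRCm38) for symbols, coordinates (counted from 1), exon length and GC content. Of 25467 genes, 25375 matched, 21179 of them with the same version, and 92 did not. No row lacked a gene name. Replicate libraries of 1 group differed by more than sampling noise, with chi-square values of 4.26 to 14.7 per degree of freedom, so none was counted as a repeat of another. Correlations of log2 CPM between libraries ranged from 0.983 to 0.992.

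The main test was edgeR 4.0.16 in R 4.3.3 on the counts, with filterByExpr, TMM normalization and a robust quasi-likelihood fit (glmQLFit, glmQLFTest) of group alone over all 7 libraries, two-sided, with Benjamini-Hochberg FDR under 0.05. A log2 fold change above 0 means higher with TSP1, and its SE was taken as the size of the log2 fold change over the square root of F. CPM are given per library with TMM scaling as mean ± SD. The depth of 15090336 to 20755167 counts per library leaves a median SE of 0.11 log2 units per gene. P-values of single genes set the group difference against the spread between mice within a group. The series describes 7 different mice, and nothing is said of shared litters or cages.

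Before the data were examined, 28 gene lists, the main tests and the rule for the genes named were fixed. The rule took Thbs1, Cacna2d1, Nlgn1, Cd47 and Lrp1 whatever their result. It then took up to 10 genes in each direction past the FDR threshold and, as fewer than 10 passed, the 10 genes of smallest p with no overlap between groups, leaving out predicted genes and clone names. Last, it took the member of smallest p in each list with no member past the threshold. A gene that the rule took is not reported here. Further members are named beside their lists and were chosen after their values were seen. Lists cover thrombospondins and receptors, synapses, interneurons, peptides, early, clock and glucocorticoid-responsive genes, glial activation, interferon response, matrix, 9 cell types, 2 regions and RNA quality. Each with at least 5 tested members (27 of 28) was tested on limma 3.58.1 voom values with camera at a preset correlation of 0.01, and also with an estimated correlation and with fry. The preset correlation takes list members as nearly independent, so its p-values leave out most of the variation between mice that members share. Per-library values of a list are means of log2 CPM (prior count 2) relative to the mean of the 7 libraries.

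Single values were compared with exact permutation tests over the 35 splits of 7 libraries into 4 and 3, two-sided, which cannot give a p below 0.0286. Alternatives fixed in advance were size factors of the RLE type, DESeq2 1.42.0 with its defaults, edgeR's exact test, limma-voom, no low-count filter, a filter of at least 5 CPM in 3 libraries, the replicate number as a block and leaving out each library in turn. DESeq2 gave no adjusted p for 9398 genes, which stayed out of its counts. Removing each library's trend with exon length and GC content (natural splines with 4 degrees of freedom each, as offsets), and DESeq2 and the exact test with single libraries left out, were added after the data were seen. The test scripts were tested on simulated counts with the means and library sizes of the real libraries. There the quasi-likelihood test, over 16982 genes, made 11 false calls beside 49 recovered 1.5-fold and 76 recovered 2-fold changes. The false share of its calls was thus above the FDR threshold of 0.05. Of the simulated lists, 3 of 3 shifted by 0.3 log2 units and 0 of 20 unshifted were called by camera with each correlation and by fry. Genes were simulated independently of each other, whereas the real lists had a median estimated correlation of 0.32. The simulated list calls therefore do not give the false calls or the power of these tests on the real lists.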

Results

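Gene expression was measured by RNA sequencing in the medial prefrontal cortex (mPFC), the midline part of the frontal cortex, of 7 mice. The labels put 4 libraries in a group treated with rhTSP1, recombinant human thrombospondin-1 (called TSP1 below), and 3 in a group given phosphate-buffered saline (PBS). The series describes 7 different mice, so each library was taken as 1 animal. Each library was made from 1.3 µg of total RNA. Dose, route, time of dissection, strain and sex are not given in the sources used here. The count table listed 25467 genes and between 15090336 and 20755167 counts per library. The mean total was 17460000 ± 1616000 counts (SD, n = 4) with TSP1 and 18270000 ± 2169000 (SD, n = 3) with PBS, a difference within the spread between libraries (exact permutation test, two-sided, p = 0.6). Between 23548 and 23895 genes had at least 1 count in a library. The biological coefficient of variation was 9.8%, and 17211 genes passed the low-count filter.

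The comparison addresses what thrombospondin-1, a secreted matrix glycoprotein that astrocytes release and that promotes the formation of excitatory synapses, does to gene expression in the mPFC. Marker transcripts of several non-neuronal cell types and transcripts of ribosomal proteins mostly had lower fitted values with TSP1. All 16 microglia markers, 15 of 16 astrocyte markers, all 14 endothelial markers and all 23 cytosolic ribosomal protein genes tested had fitted log2 fold changes below 0, with medians of -0.26, -0.17, -0.22 and -0.22. The ribosomal, microglia, astrocyte and endothelial lists passed limma's camera test with its preset correlation (adjusted p = 1.3e-15, 2.93e-11, 1.1e-08 and 1.58e-06). Each of these 4 lists had an adjusted p = 0.296 with an estimated correlation, so none of them passed there. Their means per library did not pass either (exact permutation p = 0.0571, 0.0857, 0.114 and 0.114). In TSP1 replicates 2 and 3 the microglia means were 0.01 and 0.00 log2 units from the mean of the 7 libraries and the astrocyte means 0.05 and 0.04, against -0.22 and -0.32 (microglia) and -0.22 and -0.21 (astrocyte) in TSP1 replicates 1 and 4. All PBS libraries lay above every TSP1 library in both lists, at 0.06 to 0.25 (microglia) and 0.08 to 0.18 (astrocyte).

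No single gene passed the adjustment over all genes. In edgeR's quasi-likelihood test, 0 of 17211 genes had a Benjamini-Hochberg FDR under 0.05, and the smallest FDR was 0.0536. At an unadjusted p under 0.05 there were 1661 genes, 724 higher and 937 lower with TSP1, where 861 would be expected with no effect. The groups did not overlap at 1737 genes (10.1%), against 5.71% by chance. DESeq2 called 87 genes, edgeR's exact test 85 and limma-voom 0. In counts simulated for this comparison on 16982 genes, the quasi-likelihood test recovered 76 of 98 genes changed 2-fold (77.6%) and 49 of 99 genes changed 1.5-fold (49.5%). The simulated genes were independent, and the changed ones, present together, eased the FDR threshold for each other. These shares therefore do not give the power of the test on the real libraries.

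The gene of thrombospondin-1 itself and 4 receptor genes did not pass the adjustment over all genes. Thbs1, on chromosome 2 from 118111876 to 118127133 (GRCm38; a protein-coding gene with 6073 bases of exon), had 2.01 ± 0.605 CPM (counts scaled to library size; SD, n = 4) with TSP1 and 1.57 ± 0.505 (SD, n = 3) with PBS, a log2 fold change of 0.38 (SE 0.30, adjusted p = 0.733 in edgeR). The log2 fold change of Thbs1 was 0.20 without TSP1 replicate 3, 0.21 without PBS replicate 1 and 0.66 without PBS replicate 3. Cacna2d1, the calcium channel subunit that serves as a neuronal thrombospondin receptor, lies on chromosome 5 from 15934691 to 16374511 and had 236 ± 14.1 CPM with TSP1 and 216 ± 8.01 with PBS (log2 fold change 0.13, SE 0.07, edgeR adjusted p = 0.576). Nlgn1, a postsynaptic adhesion gene on chromosome 3 from 25426215 to 26332460, had 68.6 ± 3.56 and 61.2 ± 5.99 CPM (log2 fold change 0.17, SE 0.08, edgeR adjusted p = 0.506), and of these 5 genes it alone was among the genes at an unadjusted p under 0.05. The log2 fold change of Nlgn1 was 0.09 without PBS replicate 1 and 0.09 after the length and GC correction, which left Cacna2d1 at 0.05. For Cd47 (chromosome 16, 49800533 to 49915010) and Lrp1 (chromosome 10, 127538161 to 127621148) the log2 fold changes were 0.01 (SE 0.07) and 0.05 (SE 0.09), and the sign of both turned when single libraries were left out. Of the 22 tested genes of thrombospondins and their receptors, 16 had fitted values above 0 (median log2 fold change 0.13) and the list missed the threshold in camera (adjusted p = 0.0678, and adjusted p = 0.298 with an estimated correlation). None of the 22 passed over all genes or when adjusted over the list alone. The list was called without TSP1 replicate 4, PBS replicate 2 or PBS replicate 3 (adjusted p as low as 0.0379). With the replicate block, which gives TSP1 replicate 4 no weight, the list was also called (adjusted p = 0.0447). Its median was 0.07 without PBS replicate 3, and after the length and GC correction it was also 0.07 (adjusted p = 0.356). The smallest p in it was that of Itga4, an integrin subunit gene on chromosome 2 from 79255426 to 79333123, with 22.5 ± 2.54 and 17.6 ± 0.892 CPM (log2 fold change 0.35, SE 0.10, edgeR adjusted p = 0.288).

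Of the 10 genes of smallest p taken by the rule, 9 are reported. The rule took only genes with no overlap between the groups, and all 9 failed the adjustment in edgeR's quasi-likelihood test. Higher with TSP1 were Myo16, Dcx and Reln. Myo16, an unconventional myosin gene (chromosome 8, 10153911 to 10634742), had 43.1 ± 4.85 CPM (SD, n = 4) against 28.7 ± 0.268 (SD, n = 3), a log2 fold change of 0.59 (SE 0.09, adjusted p = 0.0902). Dcx, which encodes the microtubule-binding protein doublecortin of migrating young neurons (chromosome X, 143855842 to 143933311), had 75 ± 4.44 against 50.3 ± 7.64 CPM (log2 fold change 0.57, SE 0.09). Reln encodes the secreted protein reelin (chromosome 5, 21884454 to 22344702) and had 85.7 ± 4.69 against 61.5 ± 6.81 CPM (log2 fold change 0.48, SE 0.08).

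Lower with TSP1 were mt-Tn, Ccdc85b, Rps21, Sat1, Mpeg1 and Lyz2. The mitochondrial transfer RNA gene mt-Tn (mitochondrial chromosome, 5089 to 5159, 71 bases) had the smallest p of all genes, with 22.4 ± 2.42 against 35.6 ± 2.05 CPM (log2 fold change -0.67, SE 0.09, edgeR adjusted p = 0.0536). Lyz2, a lysozyme gene of macrophages and microglia (chromosome 10, 117277331 to 117282321), had 6.53 ± 1.21 against 13.4 ± 3.29 CPM (log2 fold change -1.04, SE 0.18). Mpeg1, another macrophage and microglia gene (chromosome 19, 12460779 to 12465283), had 37.4 ± 4.57 against 53.8 ± 4.26 CPM (log2 fold change -0.52, SE 0.09). The log2 fold changes of Ccdc85b (chromosome 19, 5453180 to 5457894), Rps21 (chromosome 2, 180257377 to 180258445) and Sat1 (chromosome X, 155213132 to 155216449) were -0.42 (SE 0.07), -0.39 (SE 0.07) and -0.40 (SE 0.07). Except for mt-Tn and Myo16, each of the 9 genes had an edgeR adjusted p = 0.112. The counting method is not given in the sources used here, so Lyz2, which has the near-identical paralog Lyz1, and ribosomal protein genes with processed pseudogenes are uncertain where reads could be split between copies.

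**Figure D1:**
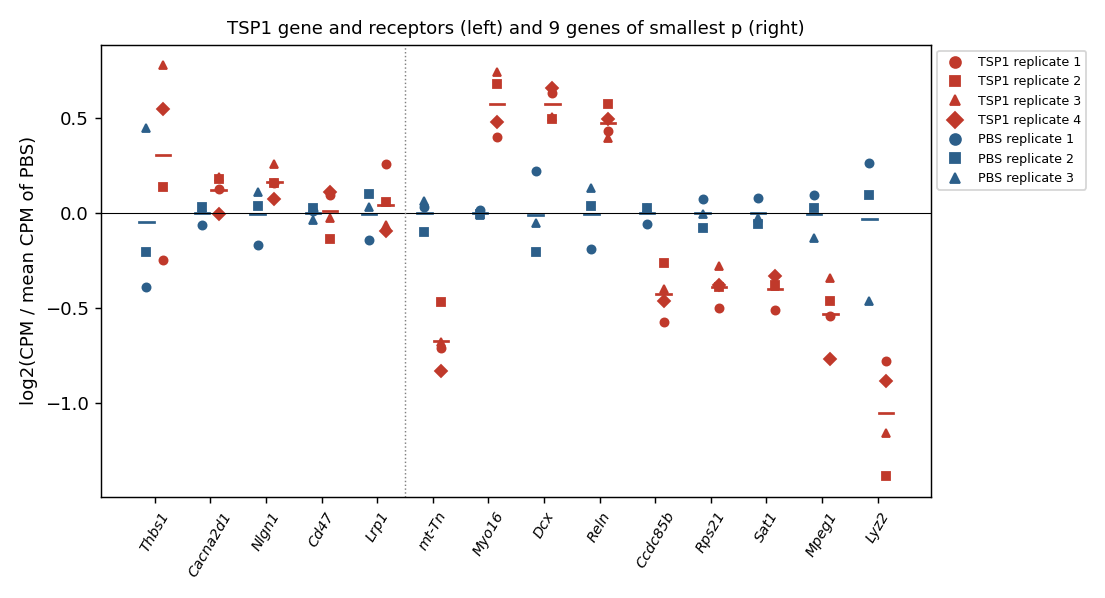
CPM of 14 genes in each library, as log2 of the ratio to the mean of the 3 PBS libraries (vertical axis). Each symbol is 1 library (red TSP1, blue PBS) and the short bars are group means of the log2 values. Left of the dotted line are Thbs1 and 4 receptor genes. Right of it are 9 genes of smallest p, taken only from genes at which the 4 TSP1 and the 3 PBS libraries do not overlap.

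DESeq2 and edgeR's exact test shared 75 called genes, 18 higher and 57 lower with TSP1, and the quasi-likelihood test gave these 75 an FDR of at most 0.328. The genes named here from the 75 were chosen after their values were seen. Among those called higher by both were Insig1 (DESeq2 adjusted p = 0.00534), a regulator of sterol synthesis, Slc17a6 (0.0229), a vesicular glutamate transporter, and Fabp7 (0.000797), a fatty acid binding protein of radial glia and astrocytes. Among those called lower by both were the endothelial gene Vwf (DESeq2 adjusted p = 2.03e-06), the acute-phase gene Lcn2 (3.11e-05), the lysosomal protease gene Ctss (0.000919), the Fc receptor gene Fcgr3 (0.00402), the astrocyte gene S100b (0.00693) and the chaperone gene Hspa5 (0.00579). The set varied with the libraries: without TSP1 replicate 4 both tests called 65 genes, 43 of them shared with the 75, and without PBS replicate 1 they called 36, of which 20 were shared.

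Immune-related lists were called lower with TSP1 by camera with its preset correlation, but not with an estimated one (adjusted p = 0.296 for the microglia list). In the microglia list 10 of 16 genes passed when adjusted over the list alone and 0 passed over all genes. C1qa, a complement component gene (chromosome 4, 136895917 to 136898803), had 39.7 ± 5.13 against 57 ± 6.64 CPM (log2 fold change -0.52, SE 0.10, edgeR adjusted p = 0.128), and Tyrobp and Trem2, a signalling adaptor and its receptor, had log2 fold changes of -0.54 (SE 0.14) and -0.43 (SE 0.12). The list of microglial activation and cytokine genes had a median log2 fold change of -0.50 over the 13 of its 24 genes that were tested (camera adjusted p = 0.00124, and adjusted p = 0.296 with an estimated correlation). Il1b, Il6, Tnf and the chemokine genes of the list were not among the 13, and Il1a had a log2 fold change of 0.33 (SE 0.38). Adjusted over the list alone 4 genes passed, Ptgs2, H2-Aa and H2-Ab1 lower and Nfkbia higher. H2-Aa and H2-Ab1 were near the floor and varied widely in PBS. H2-Aa had 0.563 ± 0.329 CPM with TSP1 against 2.67 ± 2.29 with PBS, and its groups overlapped. H2-Ab1 had 0.723 ± 0.19 against 2.81 ± 2.43 CPM. Ptgs2, a prostaglandin synthase gene (chromosome 1, 150100031 to 150108227), had 15.1 ± 2.09 against 21.5 ± 2.65 CPM (log2 fold change -0.50, SE 0.12, edgeR adjusted p = 0.171), while Nfkbia, in the same list, had a log2 fold change of 0.29 (SE 0.09). Of 19 interferon-stimulated genes, 17 had fitted values below 0 (median -0.24, camera adjusted p = 0.000114, and adjusted p = 0.296 with an estimated correlation) and 2 passed when adjusted over the list alone. Irf7 (chromosome 7, 141262706 to 141266481) had 1.89 ± 0.256 against 3.72 ± 1.27 CPM (edgeR adjusted p = 0.235). PBS replicate 2 had the highest mean of both lists, 0.74 and 0.64 log2 units above the mean of the 7 libraries, and both lists were still called without it. PBS replicate 3 was at -0.18 in the interferon list, inside the range of the TSP1 libraries (-0.24 to -0.12). Without PBS replicate 3 the median of the microglial activation list was -0.32 and that of the interferon list -0.39, and both were called.

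Astrocyte genes showed the same direction. In the astrocyte list 6 of 16 genes passed when adjusted over the list alone, among them S100b (chromosome 10, 76253853 to 76261159; 72.4 ± 7.98 against 97 ± 6.98 CPM, log2 fold change -0.42, SE 0.08, edgeR adjusted p = 0.123), Ntsr2 (-0.34, SE 0.08) and the aldolase gene Aldoc (-0.31, SE 0.09). Aqp4, the water channel of astrocyte endfeet, had a log2 fold change near 0. Of 18 reactive astrocyte genes, 13 had fitted values below 0 (median -0.18, camera adjusted p = 0.000442, and adjusted p = 0.244 with an estimated correlation), and 4 passed when adjusted over the list alone. They were Lcn2, Serpina3n, C4b and Osmr, with log2 fold changes of -1.99 (SE 0.34), -0.69 (SE 0.17), -0.60 (SE 0.14) and -0.46 (SE 0.16). Lcn2 (chromosome 2, 32384633 to 32388252) had 1.52 ± 0.571 against 6 ± 2.29 CPM (edgeR adjusted p = 0.117). The mean of the reactive astrocyte list lay below 0 in all 4 TSP1 libraries and above 0 in all 3 PBS libraries (exact permutation p = 0.0286, the smallest that 35 splits can give, and 0.319 adjusted over 28 lists). The means of the astrocyte marker list did not overlap between groups either (TSP1 up to 0.05, PBS from 0.08). In TSP1 replicates 2 and 3 they lay above 0, however, and the group difference did not pass (exact permutation p = 0.114).

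Among the vascular lists, camera called the endothelial list with all 7 libraries (adjusted p = 1.58e-06, but adjusted p = 0.296 with an estimated correlation) and not the pericyte list, and the difference between them was not tested here. In the endothelial list 3 of 14 genes passed when adjusted over the list alone, and these were the tight junction gene Cldn5 (chromosome 16, 18776847 to 18778262; 28.2 ± 2.37 against 40.3 ± 7.9 CPM, edgeR adjusted p = 0.217), Ly6a and Ly6c1. Without TSP1 replicate 4 the endothelial median was -0.13 and the list was called with the preset correlation. Pericyte and smooth muscle markers had a median log2 fold change of -0.01 over 10 genes (camera adjusted p = 0.809, and adjusted p = 0.886 with an estimated correlation), and their gene of smallest p, Pdgfrb (chromosome 18, 61045150 to 61085061), was the other way, with 32.8 ± 2.43 against 27.5 ± 0.213 CPM. The meningeal fibroblast (camera adjusted p = 0.372), choroid plexus and ependymal (0.656) and blood (0.2) lists were not called, with adjusted p = 0.793, 0.87 and 0.675 with an estimated correlation. Their genes of smallest p were Lum (chromosome 10, 97565128 to 97572703; 2.23 ± 0.363 against 1.4 ± 0.205 CPM), Aqp1 (chromosome 6, 55336432 to 55348555; 1.66 ± 1.13 against 0.701 ± 0.48 CPM) and Ptprc (chromosome 1, 138062861 to 138175708; 5.91 ± 0.573 against 7.96 ± 0.273 CPM), with edgeR adjusted p = 0.413, 0.621 and 0.332. Without TSP1 replicate 3 the meningeal and blood lists were called, as was the meningeal list without PBS replicate 1 and the blood list without PBS replicate 2 (adjusted p as low as 0.00488 and 5.14e-07). In the blood list the median of 0.29 and the mean of 0.18 were above 0 while camera's direction was lower.

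**Figure D2:**
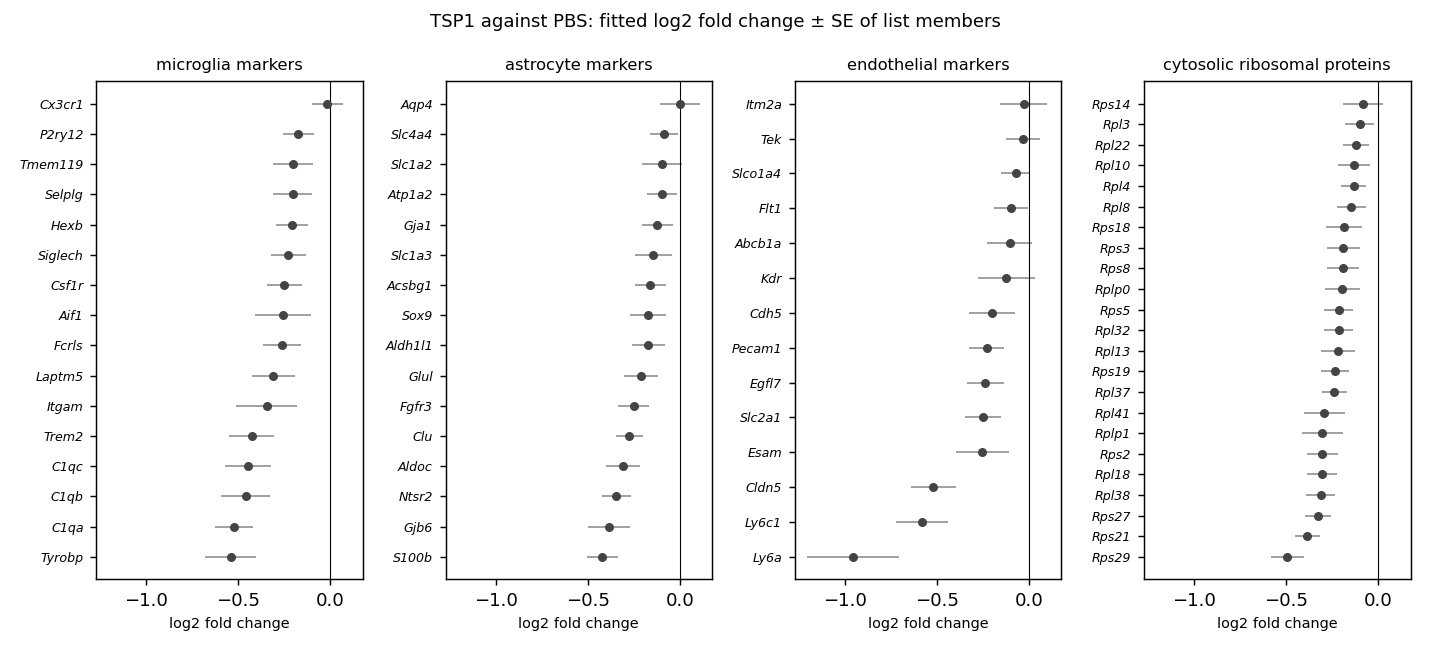
Fitted log2 fold changes of TSP1 against PBS (horizontal axis, log2 units) for the tested members of 4 lists, 1 point per gene with bars of 1 SE. All microglia, endothelial and ribosomal protein genes lie below 0, as do 15 of 16 astrocyte genes, and no single gene passed the adjustment over all genes.

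Both oligodendrocyte lineage lists were called lower with TSP1 by camera. Of 12 precursor genes 10 had fitted values below 0 (median -0.17, camera adjusted p = 0.000442, and adjusted p = 0.296 with an estimated correlation), and 2 passed when adjusted over the list alone. These were Gpr17, a receptor gene of committed precursors (chromosome 18, 31942997 to 31949636; 83.4 ± 4.86 against 102 ± 10 CPM, edgeR adjusted p = 0.235), and Neu4. Without TSP1 replicate 1 the median of the oligodendrocyte precursors was -0.085 and the list was called. The myelin list had a median of -0.14 (camera adjusted p = 0.013, and adjusted p = 0.675 with an estimated correlation), and 0 of its 15 genes passed when adjusted over the list alone. That call was lost without TSP1 replicate 1, TSP1 replicate 2 or PBS replicate 1, with adjusted p up to 0.407, and without TSP1 replicate 4 the median was -0.53. The mean of the myelin list in TSP1 replicate 4 was 0.82 log2 units above the mean of the 7 libraries, against -0.52, -0.57 and -0.18 in the other TSP1 libraries. Trf, the transferrin gene (chromosome 9, 103204001 to 103230444), had 3.11 ± 1.53 against 5.08 ± 0.596 CPM (edgeR adjusted p = 0.464). The same library stood apart in striatal markers, of which 14 of 15 were highest there. The striatal list (median 0.51, camera adjusted p = 0.00321, and adjusted p = 0.625 with an estimated correlation) was not called without it (median -0.02, adjusted p = 0.852). Its gene of smallest p was Rarb (chromosome 14, 16430839 to 16819156; 8.94 ± 2.69 against 6.28 ± 0.636 CPM, edgeR adjusted p = 0.448). Cortical layer markers were not called (median 0.03, camera adjusted p = 0.643, and adjusted p = 0.793 with an estimated correlation), and Etv1 (chromosome 12, 38779380 to 38870484) had the smallest p among them, with 63.3 ± 7.22 against 53.9 ± 12 CPM.

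**Figure D3:**
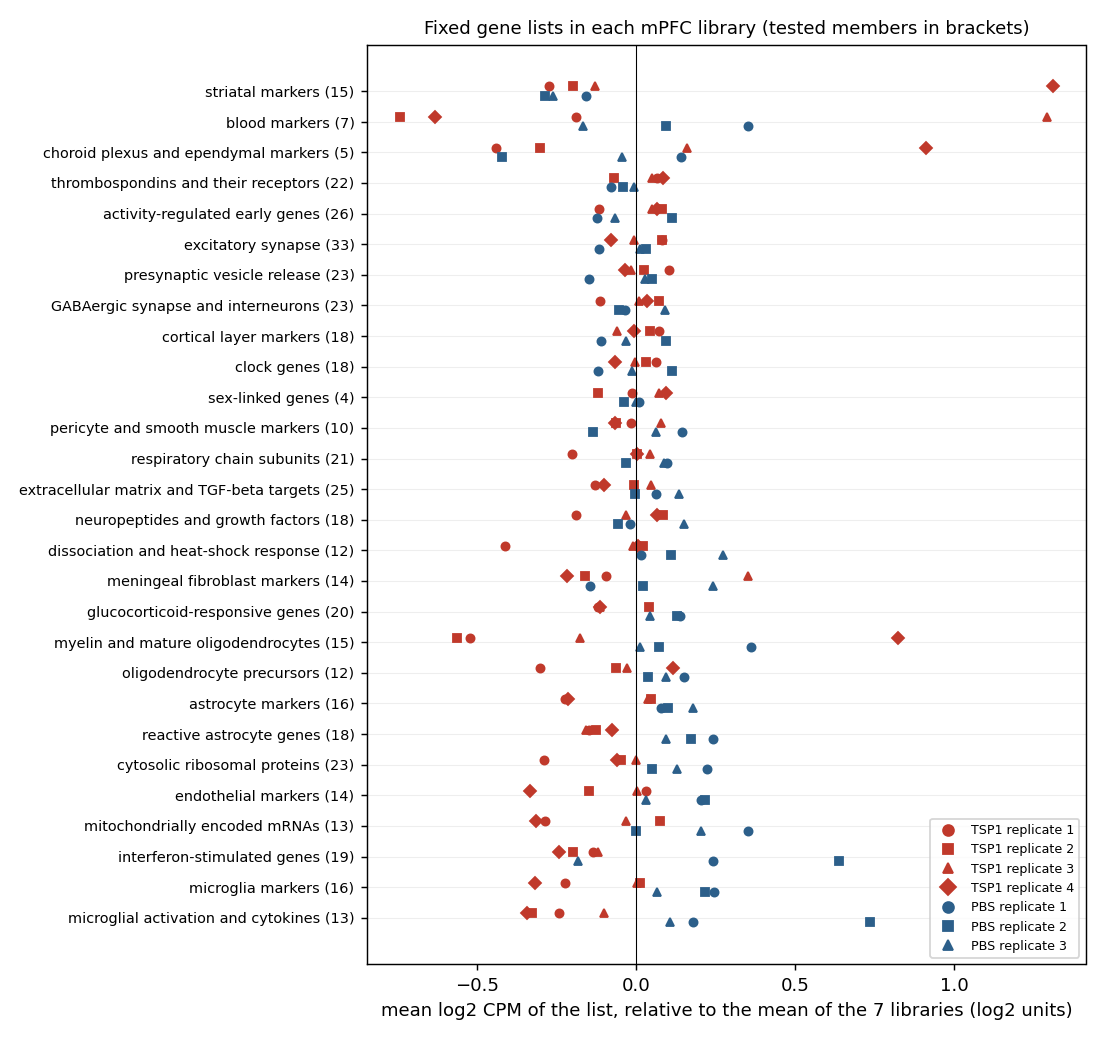
Mean log2 CPM of each fixed gene list in each library, relative to the mean of the 7 libraries (horizontal axis, log2 units), with the lists ordered by median log2 fold change. Each symbol is 1 library (red TSP1, blue PBS). TSP1 replicate 4 stands apart in striatal markers (1.31), choroid plexus and ependymal markers (0.91) and myelin genes (0.82). TSP1 replicate 3 stands apart in blood markers (1.29), and PBS replicate 2 in microglial activation (0.74) and interferon-stimulated genes (0.64).

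Synaptic lists changed little. Of 33 excitatory synapse genes 21 had fitted values above 0 (median 0.05, camera adjusted p = 0.0265, and adjusted p = 0.658 with an estimated correlation), and the call was lost without TSP1 replicate 1, TSP1 replicate 2 or PBS replicate 1 (adjusted p up to 0.648), and after the length and GC correction (adjusted p = 0.356). Slc17a6 (chromosome 7, 51622006 to 51671119) alone passed when adjusted over the list alone, with 14 ± 1.14 against 9.45 ± 0.942 CPM (log2 fold change 0.56, SE 0.11, edgeR adjusted p = 0.123). The glutamate receptor genes Grm5, Gria2 and Grin2b had log2 fold changes of 0.19 (SE 0.06), 0.18 (SE 0.07) and 0.22 (SE 0.09). Presynaptic vesicle genes were not called (median 0.04, camera adjusted p = 0.131, and adjusted p = 0.736 with an estimated correlation), although they were called without TSP1 replicate 4, PBS replicate 2 or PBS replicate 3 (adjusted p as low as 0.00675). Their gene of smallest p, Sv2a (chromosome 3, 96181151 to 96195521), had 449 ± 15.5 against 405 ± 13.5 CPM (edgeR adjusted p = 0.476).

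Interneuron genes moved both ways. The GABAergic list had no common direction (median 0.04, camera adjusted p = 0.919, and adjusted p = 0.962 with an estimated correlation), and limma's fry test for changes in either direction gave an adjusted p = 0.0218. In this list 5 of 23 genes passed when adjusted over the list alone, Reln higher and Vip, Npy, Sst and Pvalb lower. Vip, Npy and Sst encode interneuron peptides and Pvalb a calcium-binding protein, and their log2 fold changes were -0.52 (SE 0.13), -0.25 (SE 0.07), -0.21 (SE 0.07) and -0.38 (SE 0.13). Npy (chromosome 6, 49822710 to 49829507) had 49.2 ± 2.48 against 58.5 ± 2.51 CPM (edgeR adjusted p = 0.271). Of 18 neuropeptide and growth factor genes 13 had fitted values below 0 (median -0.10, camera adjusted p = 0.0238, and adjusted p = 0.577 with an estimated correlation), Npy alone passed when adjusted over the list alone, and the call was lost without TSP1 replicate 1 or PBS replicate 3 (adjusted p up to 0.44) and after the length and GC correction (adjusted p = 0.0513).

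Activity-regulated early genes were not called (median 0.05, camera adjusted p = 0.2, and adjusted p = 0.675 with an estimated correlation), and 2 of 26 passed when adjusted over the list alone, Ptgs2 with the lower and the transcription factor gene Egr2 with the higher level in TSP1 (log2 fold change 0.47, SE 0.13). Without PBS replicate 2, and after a length and GC trend was removed, the list was called higher (adjusted p = 0.00208 and 0.0254). Clock genes were not called (camera adjusted p = 0.656, and adjusted p = 0.886 with an estimated correlation), although they were called without PBS replicate 2 (adjusted p = 0.0224), and Nr1d1 (chromosome 11, 98767932 to 98775333) had 104 ± 6.21 against 84.9 ± 12 CPM (edgeR adjusted p = 0.31). Glucocorticoid-responsive genes had a median of -0.14 (camera adjusted p = 0.0185, and adjusted p = 0.296 with an estimated correlation), and 5 of 20 passed when adjusted over the list alone. Lcn2, Fam107a, Zbtb16 and Plin4 were lower, the last 3 with log2 fold changes of -0.41 (SE 0.09), -0.43 (SE 0.12) and -0.46 (SE 0.16), and Nfkbia was higher. The call was lost without TSP1 replicate 1, TSP1 replicate 4 or PBS replicate 1 (adjusted p up to 0.0793) and after the length and GC correction (adjusted p = 0.0509). With a single library left out the median of the glucocorticoid-responsive genes ranged from -0.19 to -0.07. Of 25 extracellular matrix and TGF-beta target genes, 15 had fitted values below 0 (median -0.09, camera adjusted p = 0.0197, and adjusted p = 0.296 with an estimated correlation) and 0 passed when adjusted over the list alone. Tgfb1, whose latent product thrombospondin-1 is known to activate (chromosome 7, 25687002 to 25705077), had 5.77 ± 0.692 against 8.08 ± 0.762 CPM (log2 fold change -0.49, SE 0.15, edgeR adjusted p = 0.311). That list's call was lost without TSP1 replicate 1, TSP1 replicate 4 or PBS replicate 3 (adjusted p up to 0.119), and with the replicate block (adjusted p = 0.0538). With a single library left out its median ranged from -0.12 to -0.02.

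The ribosomal, mitochondrial, respiratory chain and heat-shock lists were called lower by camera with its preset correlation. Whether they follow RNA composition or tissue handling was not tested. None of these lists passed with an estimated correlation (adjusted p = 0.296 for the ribosomal list). The list means per library did not pass for any of them (exact permutation p = 0.0571, 0.114, 0.286 and 0.143). In the ribosomal protein list 12 of 23 genes passed when adjusted over the list alone, led by Rps21 (69.5 ± 4.36 against 90.8 ± 4.78 CPM) and Rps29 (log2 fold change -0.49, SE 0.09). All 13 mitochondrially encoded mRNAs had fitted values below 0 (median -0.24, camera adjusted p = 1.58e-06, and adjusted p = 0.296 with an estimated correlation) and 0 passed when adjusted over the list alone. Levels of the 13 ranged with TSP1 from 19940 CPM (mt-Co1) to 1.94 (mt-Atp8), and the cause was not tested. In the PBS libraries mt-Co2 and mt-Atp6 varied widely (210 ± 160 and 151 ± 107 CPM). mt-Nd1 (mitochondrial chromosome, 2751 to 3707) had 5424 ± 590 against 6479 ± 249 CPM (edgeR adjusted p = 0.401). Mitochondrial genes took 5.47 ± 0.625% of the counts (SD, n = 4) with TSP1 and 6.43 ± 0.173% (SD, n = 3) with PBS (exact permutation p = 0.0857). Without TSP1 replicate 4 the median of the mitochondrially encoded mRNAs was -0.16 and the list was called. Nuclear-encoded respiratory chain subunits had a median of -0.07 (camera adjusted p = 0.00214, and adjusted p = 0.625 with an estimated correlation), with 18 of 21 below 0 and a call that was lost without TSP1 replicate 1 or PBS replicate 1 (adjusted p up to 0.258). Ndufa2 (chromosome 18, 36742332 to 36744557) had 38.6 ± 2.91 against 46.9 ± 2.78 CPM (edgeR adjusted p = 0.279). Dissociation and heat-shock genes had a median of -0.13 (camera adjusted p = 0.0265, and adjusted p = 0.577 with an estimated correlation) and were not called without TSP1 replicate 1, PBS replicate 2 or PBS replicate 3 (adjusted p up to 0.408). In that list Hspa5, the chaperone BiP of the endoplasmic reticulum (chromosome 2, 34771970 to 34777547), alone passed when adjusted over the list alone, with 187 ± 19.8 against 243 ± 9.08 CPM (log2 fold change -0.38, SE 0.08, edgeR adjusted p = 0.134). The 4 tested sex-linked genes were too few for a list test, and the Y-linked gene Kdm5d (chromosome Y, 897788 to 956786) had 46.1 ± 2.26 and 42.6 ± 2.07 CPM in the groups. Kdm5d had at least 40.3 CPM in every library, so each held RNA from a male.

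Across the 27 lists tested, camera with its preset correlation of 0.01 called 17, 2 higher (excitatory synapse and striatal markers) and 15 lower. With an estimated correlation, whose median over the lists was 0.32, 0 of 27 were called and the smallest adjusted p was 0.244. That was the reactive astrocyte list, whose own estimated correlation was -0.00374, below the preset one. Its unadjusted camera p was 0.00902 there and 0.000131 with the preset correlation. A higher correlation among members therefore does not account for every lost call. The fry test for a common direction called 0 (smallest adjusted p = 0.151), and its test for changes in either direction called 4, the GABAergic (adjusted p = 0.0218), glucocorticoid-responsive (0.00533), reactive astrocyte (0.0433) and microglial activation lists (0.0433). Without TSP1 replicate 4, the library with raised striatal and myelin genes, 16 lists and 0 genes were called, and without TSP1 replicate 1, 10 lists, of which 9 were lower. Over their lists alone 58 memberships passed and over all genes 0. The slope on transcript length was taken of each library's log2 CPM relative to the mean of the 7 libraries, so its sign is relative. Per doubling of length it was 0.00706 to 0.0158 log2 units in the 4 TSP1 libraries. In the 3 PBS libraries it was -0.0282 to -0.000355 (exact permutation p = 0.0286, the smallest that 35 splits can give). With the genes in 5 groups of equal size by exon length, the median log2 fold change was -0.06 in the shortest and 0.05 in the longest genes. In a principal component analysis, component 1 (26.2% of the variance) did not separate the groups (exact permutation p = 0.257) and component 2 (20.4%) did (exact permutation p = 0.0286, the smallest possible).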

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

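The outlier test and the lists it ran on followed rules fixed before the data were examined, and the test of a tissue source was chosen only after the result was seen. In the TSP1 group of 4, 70 values (named genes, list means and library measures) were searched for a library far from the other 3, and 6 such values were found, where chance alone gives about 3.5. The PBS group of 3 was too small for this search.

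Neighbouring striatum and white matter in the dissected piece may account for TSP1 replicate 4. Its mean of the striatal markers was 1.31, against -0.27 to -0.13 in the other TSP1 libraries (gap over range 0.909). Its mean of the choroid plexus and ependymal markers was 0.91, against -0.44 to 0.16 there, which the outlier test did not flag. In this library 14 of 15 striatal and 14 of 15 myelin genes were highest, by a median of 2.46-fold and 2.02-fold over the mean of the other 6, while cortical layer markers were not raised (median log2 difference -0.01). Drd2, a dopamine receptor gene of striatal neurons, had 16.5 CPM against 1.71 ± 0.378 (SD, n = 6), Adora2a 19.3 against 2.88 ± 0.404, Penk 86.1 against 29.3 ± 6.58 and the myelin gene Mbp 3790 against 1970 ± 433. Its Trf was far above the other TSP1 libraries (2.43 log2 CPM against 1.17 to 1.31, gap over range 0.891) but not above PBS, with 5.39 CPM against 5.35, 5.50 and 4.40 in the PBS libraries. A wrong label and a response of 1 treated mouse were not tested and stay open.

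TSP1 replicate 1 was low in activity-regulated early genes (-0.12 against 0.05 to 0.08 in the other TSP1 libraries, gap over range 0.853), in respiratory chain subunits (-0.20 against 0.00 to 0.04, gap over range 0.838) and in dissociation and heat-shock genes (-0.41 against -0.01 to 0.02, gap over range 0.93). TSP1 replicate 2 was high in glucocorticoid-responsive genes (0.04 against -0.12 to -0.11, gap over range 0.961).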

How the results depend on the processing

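The alternatives were fixed before the data were examined, except the removal of the length and GC trend and the DESeq2 and exact tests with single libraries left out, which were chosen only after results were seen. Directions of the 39 named genes held in every alternative in which they were tested except for Cd47 and Lrp1. The count of 0 genes past the FDR threshold (higher and lower also 0) stayed at 0 with RLE size factors, limma-voom, the stricter filter, the block and the length and GC correction. It was 87 with DESeq2 (21 higher, 66 lower), 85 with the exact test (21 and 64) and 19 without the low-count filter (7 and 12), and the cause was not tested. Leaving out single libraries gave 0 to 9 genes, 0 to 1 higher and 0 to 9 lower: without PBS replicate 3, 9 genes lower (among them Lcn2, Cldn5 and Vwf), without TSP1 replicate 2 only mt-Tn, and without PBS replicate 1 only Dcx. Genes at an unadjusted p under 0.05 numbered 1181 to 2083 over all alternatives.

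The 17 lists called by camera became 0 with an estimated correlation and 0 with fry, 10 to 21 with single libraries left out (10 without TSP1 replicate 1), 17 with RLE size factors and 15 after the length and GC correction. Of the 17, 9 were called in all 7 fits with a library left out: reactive astrocyte, microglial activation, interferon-stimulated, precursor, astrocyte, microglia, endothelial, mitochondrial and ribosomal. With a library left out, log2 values that changed sign ranged from -0.0167 to 0.0651 for Cd47, -0.0291 to 0.107 for Lrp1, and for list medians from -0.0105 to 0.0775 (presynaptic), -0.0125 to 0.081 (GABAergic), -0.0472 to 0.0711 (clock), -0.534 to 0.0291 (myelin), -0.084 to 0.0517 (pericyte), -0.259 to 0.019 (meningeal), -0.739 to 0.587 (blood), -0.0571 to 0.0686 (cortical layer) and -0.0225 to 0.608 (striatal). The choroid plexus list could not be tested without TSP1 replicate 4, where fewer than 5 members passed the filter. After the length and GC correction Cd47 was -0.0299.

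Replicate numbers 1 to 3 occur in both groups, but samples sharing a number did not deviate together (correlations -0.261, -0.033 and 0.01), and not every sample correlated best with its own number. With the replicate number as a block, 0 genes and 17 lists were called, 15 of them among the 17 called without it. Values turned sign for Cd47 (-0.0223) and the GABAergic (-0.00815), choroid plexus (-0.336) and striatal (-0.0503) medians. TSP1 replicate 4 alone has number 4, so its own block absorbs it and it has no weight in this comparison. The block is therefore not a check apart from leaving out that library. Pseudocount settings for normalized values did not apply to counts and were not run. At this depth the SE of a low gene such as Thbs1 (0.30) was above the median of 0.11. In the simulation of independent genes 49 of 99 1.5-fold changes were recovered, a share that need not hold for the real libraries.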

Other observations

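The lists of sterol, endoplasmic reticulum and thalamic genes, the split counts of genes past the FDR threshold and of lists by direction, and the test for a shared fall of non-neuronal markers were chosen only after results were seen. Genes of sterol metabolism mostly had fitted values above 0 with TSP1. Genes such as Insig1 (64 ± 6.26 against 48.2 ± 0.635 CPM) had drawn attention among those of small p and were left out of the list test. In the rest of a list of targets of the sterol-sensing transcription factor SREBP2, 16 of 17 genes had fitted values above 0, 8 of them at an unadjusted p under 0.05, with a median log2 fold change of 0.18. Lss, Mvd and Sqle, enzymes of the pathway, had log2 fold changes of 0.25 (SE 0.07), 0.29 (SE 0.11) and 0.18 (SE 0.06).

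Chaperones and folding enzymes of the endoplasmic reticulum mostly had fitted values below 0. Hspa5, Pdia4, Xbp1, Sdf2l1 and Manf had drawn attention, and in the rest of a list of unfolded protein response genes 13 of 15 did, 4 of them at an unadjusted p under 0.05, with a median log2 fold change of -0.09 (limma's camera p = 0.08 with an estimated correlation). These 4, Pdia6, Dnajc3, Dnajb11 and Herpud1, had log2 fold changes of -0.28 (SE 0.07), -0.27 (SE 0.07), -0.23 (SE 0.06) and -0.23 (SE 0.07).

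A shared rise of sterol genes with TSP1 is a hypothesis found and tested on the same mice. Without the genes that drew attention, limma's fry test gave p = 0.00644 (adjusted p = 0.0193 over the 3 added lists), and camera p = 0.0191 with an estimated correlation. After removal of the length and GC trend the fry p was 0.00642, and with single libraries left out it ranged from 0.00506 to 0.0216, which argues against a length trend or 1 library as the whole source. Of 35 splits of the 7 libraries only the real one (1) had a median as high (0.18, highest other 0.12), a share of 0.0286, the smallest that 35 splits can give. That count was in 1 direction. In the other direction, the split of TSP1 replicate 2 with the 3 PBS libraries came close in size, with a median of -0.165. As the list and its direction were chosen after sterol genes had stood out in these libraries, the splits do not exclude chance in that choice. TSP1 may raise these genes, but an effect of processing order cannot be separated from treatment here and was not tested.

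Without TSP1 replicate 1 the median of the endoplasmic reticulum list was -0.06. For this list the hypothesis of a shared fall gave a fry p = 0.0188 (adjusted p = 0.0282 over the 3 added lists only) and a camera p = 0.08 with an estimated correlation. The fry p was 0.0658 without PBS replicate 2 and 0.0621 without PBS replicate 3. Of the 35 splits, 3 had a median as low (-0.09, lowest other -0.10), so chance cannot be excluded. Slc17a6 and Ntng1, genes abundant in thalamic neurons, were higher with TSP1, and thalamic tissue in the pieces was tested with 12 other thalamic markers. Their median log2 fold change was 0.05 with an adjusted p = 0.645 in limma's fry test and 0 of them reached an unadjusted p under 0.05 in either direction, which argues against thalamic tissue as the source.

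The 15 lists lower with TSP1 were weighed against 3 technical readings. A trend with transcript length or GC content is argued against as the whole source, since removing it kept 91.5% of the median log2 fold change of the lists' 251 genes (78.7 to 96.3% over resampled lists) and 13 of the lists stayed called lower with the preset correlation. A single library is argued against as the whole source, since at least 14 of the 15 lists kept a median below 0 whichever library was left out. Their size did depend on single libraries: without TSP1 replicate 1, 9 lists were called lower and the respiratory chain and heat-shock medians were -0.0184 and -0.0358, and without PBS replicate 3 the neuropeptide median was -0.00386. A lower share of non-neuronal cells stays open. It would lower 6 cell type lists alike. Their differences in list mean ran from -0.31 (microglia) to -0.04 (pericytes), a wider gap (0.27) than the reading was set to allow. That gap was within the largest of other splits of the libraries (up to 0.77, exact permutation p = 0.857), so 7 libraries do not decide it. The splits could hardly reject the reading, since the myelin mean alone ran from -0.57 (TSP1 replicate 2) to 0.82 (TSP1 replicate 4). In number of lists lower in the group of 4, only the real split (1 of 35) gave 15, with a highest other of 13, but that direction was chosen after the fall was seen, so this count decides nothing. Whatever the direction, 2 of 35 splits gave as many lists in 1 direction, the other (also 15) setting TSP1 replicate 3 with the 3 PBS libraries. Chance stays open, and 4 of the 35 splits called as many lists in all (17, highest other 18), 23 of the other splits called at least 10, and with an estimated correlation 0 lists were called.

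For the quasi-likelihood count of 0 genes the splits decide nothing, since every split gives at least 0. All 35 gave as many genes, as many higher (35) and as many lower (35), and the highest others were 20, 20 and 1. The 20 genes came from a split of TSP1 replicates 2, 3 and 4 with PBS replicate 1 against the rest, and whether the libraries have a structure along it was not tested. For the other counts of genes chance cannot be excluded. At an unadjusted p under 0.05, 2 of 35 splits gave as many genes as the real 1661, the other (1803) setting TSP1 replicate 2 with the 3 PBS libraries. For DESeq2, 4 of 35 splits gave at least the real 87 genes (highest other 126), for the exact test 2 of 35 gave at least 85 (highest other 106), and for genes called by both tests 2 of 35 gave at least 75 (highest other 77).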
